A study of Homo sapiens with 36 samples.

How the data were processed

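The series holds 36 Affymetrix HG-U133A arrays of normal human tissues, 1 array per tissue, and its title names their expression profiles as the subject. The labels give the tissue and nothing on donors or on pooling of RNA. The deposited table gives 1 intensity per probe set and array for 22283 probe sets on a linear scale. Every array had a mean of 100 after trimming 2% of its values at each end, and the deposited scale was kept. The summary algorithm, the background correction and the detection calls are not given in the sources used here. An experiment record of each array, written by the instrument per the file headers, gave chip lots (30 arrays of lot A, 5 of lot B, 1 of lot C), 9 scan days and 6 arrays with a stopped fluidics record. Scan days are numbered in order and no record was used for anything but batches.

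All 36 columns matched a sample. Of the probe sets, 68 were controls, 19071 had 1 gene symbol, 1043 had several and 2107 had none in the annotation table, which dates from 2016. Through the gene identifier 19059 symbols were updated and 12 were kept as given. Probe sets with several or no symbols were left out, since they cannot be assigned to 1 gene. Each of 11929 genes was represented by its probe set with the highest mean over the 36 arrays, out of at least 2 probe sets for 4299 genes. Of the chosen probe sets 860 end in _x_at and 3988 in _s_at, types that can hybridise to several transcripts. No genome build comes with the table, so no positions are given. A gene was tested if its highest value exceeded 48.1, the median of all values, which kept 10916 genes and removed 1013. Values were taken as log2 of the intensity plus 15.1, the 25th percentile of all values, and 3 values were equal to 0. Fold differences are those of the intensity plus this pseudocount. The share of values below the pseudocount ran from 22.0% in trachea to 28.7% in skeletal muscle.

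Tissues were grouped by anatomical class from their labels: 8 central nervous system, 3 haematolymphoid, 3 digestive tract and 2 striated muscle tissues. Each class was compared with all other tissues, and the corpus array entered neither side. Fetal brain, lung and liver were compared with brain, lung and liver with organ as a block, 3 arrays against 3 with 2 residual degrees of freedom. Genes were tested two-sided with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. They were called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold difference, and every adjusted p of a gene is from limma. The tissues of a class served as its replicates, so the spread of a class holds differences between its tissues. Each gene had a common spread, pooled over both sides of a class comparison with 33 residual degrees of freedom. For haematolymphoid, digestive tract and striated muscle tissues nearly all of it came from the other tissues. A p-value there says little on whether the class tissues are alike, and a gene high in a single class tissue could pass.

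In the classes 52 gene lists were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, all from limma, and adjusted over the lists of a comparison. Members were also counted with p-values adjusted over the list alone. The lists, the comparisons, the rule for named genes and all alternatives but 4 were fixed before the data were examined. Tissue-enriched genes had an intensity plus pseudocount of at least 5 times that of the next tissue, region-enriched genes at least 3 times that of the next of 8 regions, and heart and skeletal muscle were compared at 8-fold. For marker lists of single tissues the median log2 difference from the median of the other tissues was ranked among 10000 random lists of the same size, matched on mean expression. Breadth was the number of tissues with a value above 48.1, with the tau index beside it, and similarity was the Spearman correlation across genes.

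For each class and direction the 12 called genes with the largest log2 difference were named, and where fewer passed, up to 4 that did not pass were named as such. For the fetal comparison the 12 per direction with the largest mean difference were named among genes changed at least 2-fold the same way in all 3 organs. In each list described, the 3 members with the largest and the 1 with the smallest absolute difference could be named. For enriched genes the 3 largest ratios were named per tissue with at least 5 such genes and per region, and for heart against skeletal muscle the 6 largest per direction. Further list members named in the fetal comparison, in the prostate array and in the corpus array were chosen after their values were seen. Y-linked genes, the X inactivation transcripts and a fixed set of genes whose level follows an allele of single donors were left out of all tests and are not named. Other X-linked genes stayed in, and the labels do not give the sex of the donors.

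Alternatives changed 1 choice at a time. They were quantile normalization, pseudocounts of 3.775 and 60.4, no filter and a stricter filter on dim genes, all probe sets, the probe set with the largest variance, trend and robust variance in limma and no minimum fold. Further alternatives left out each tissue of a class in turn, other tissues that resemble a class, or blocked on scan day or chip lot. The 4 alternatives added after seeing the data used the GAPDH or the actin 3′ to 5′ ratio as a covariate, or left out the 6 arrays with a stopped fluidics record or the 5 arrays with a GAPDH ratio above 2. The test was also tried on simulated data with 50 changed genes per size. Each gene had its residual spread in the real arrays, equal on both sides, and genes were drawn independently. Recovery may be lower where a class spreads more than the other tissues. At a true log2 difference of 2 the test recovered 98% of genes for the central nervous system, 82% for haematolymphoid and for digestive tract tissues, 74% for striated muscle and 0% for the fetal comparison. At a true log2 difference of 4 it recovered 100%, 100%, 94%, 96% and 50%. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.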

Results

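RNA from 36 normal human tissues was measured on Affymetrix HG-U133A arrays, with 1 array per tissue. No tissue had a replicate, so every value of a single tissue is given without an error, and the number of arrays limits the precision. The labels placed 8 tissues in the central nervous system: amygdala, brain, caudate nucleus, cerebellum, fetal brain, hippocampus, spinal cord and thalamus. Bone marrow, spleen and thymus made up 3 haematolymphoid tissues, colon, small intestine and stomach 3 digestive tract tissues, and heart and skeletal muscle 2 striated muscle tissues. Brain, lung and liver each came as a fetal and a non-fetal array. The label "corpus" named no organ, and that array entered no class. Values were linear intensities. The array medians ran from 40.4 in skeletal muscle to 53.5 in breast, and the highest value of an array ran from 4785 in spinal cord to 16949 in bone marrow. The ratio of the 3′ to the 5′ probe set of GAPDH, a measure of RNA integrity and labelling, had a median of 1.20 and ran from 0.819 in fetal lung to 2.65 in pituitary gland. Of the 11929 genes with a probe set of their own, 10916 were tested. Each class was compared with all other tissues to find the genes that set it apart, and p-values measure the spread between tissues, not between donors. Outside the central nervous system comparison that spread was mostly that of the other tissues, so a gene high in a single class tissue could pass. Folds and log2 differences were taken with a pseudocount of 15.1 added to each value, so where either side lay below 15.1 their size depends on it.

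Myelin, astrocyte and neuronal transcripts set the central nervous system apart. MBP, a structural protein of myelin, lay at a mean log2 intensity of 11.84 ± 0.53 (SD, n = 8) in the central nervous system and at 5.73 ± 0.77 (SD, n = 27) in the other tissues, a 69.1-fold difference (adjusted p = 2.45e-19). All 8 tissues lay above every other tissue, from 1540 in fetal brain to 4685 in thalamus, and the next tissue was skeletal muscle at 244.3. GFAP, the intermediate filament of astrocytes, was 55.1-fold higher (11.18 ± 0.40 against 5.39 ± 0.72, SD, n = 8 and 27, adjusted p = 1.01e-19). STMN2, a microtubule regulator of neurons, lay at 588.5 to 2881 against a median of 5.1 in the other tissues, and SNAP25, a protein of the synaptic fusion machinery, was 34.9-fold higher. Lower in the central nervous system were COL6A3, a collagen chain 15.4-fold lower (5.23 ± 0.88 against 9.18 ± 1.39, SD, n = 8 and 27, adjusted p = 5.77e-08) and CDH1, the adhesion protein E-cadherin, with a log2 difference of −3.58. In all, 1061 genes were higher and 685 lower. The other genes with the largest differences upward were APLP1, NEFL, GPM6B, RTN1, SYNGR3, ENO2, GAP43 and NDRG4, at log2 differences from 4.73 (NDRG4) to 5.40 (APLP1). NEFL encodes a neurofilament subunit and GAP43 a growth cone protein. SNAP25 reached 675.8 in pituitary gland and NDRG4 1299 in heart, the highest values of these genes outside the class.

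The synaptic, receptor, channel, astrocyte and oligodendrocyte lists lay higher in the central nervous system. All 16 tested genes of the synaptic vesicle and release list passed as higher, with a median log2 difference of 3.36. SYNGR3 (4.94) and SV2A (4.32) were among the largest and UNC13A (1.04, adjusted p = 5.23e-07) was the smallest. Among oligodendrocyte and myelin genes 12 of 13 were higher (median 2.77), including TF (4.37) and MOBP (3.64), while CLDN11 lay at 0.36 (adjusted p = 0.136). Among astrocyte genes 10 of 15 were higher (median 2.44), including S100B (4.40) and TTYH1 (4.02), while EDNRB lay at 0.05. Among glutamate and GABA receptors and GABA synthesis 12 of 18 were higher (median 1.94), including the AMPA receptor subunit GRIA2 (4.40), the GABA-synthesising enzyme GAD1 (4.31) and GRM3 (3.13), while GABRB2 lay at 0.00. Of 13 neuronal voltage-gated channels 9 were higher (median 1.34), with CACNA1A at 2.29, SCN3A at 2.26 and KCNAB2 at 2.19, while KCNA1 lay at −0.03. These 5 lists passed the set test camera (adjusted p from 2.46e-23 to 3.79e-08) and also with an estimated correlation (adjusted p from 2.09e-07 to 0.0075), and the counts were equal when adjusted over the list alone.

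Lists fixed for cerebellum, caudate nucleus and fetal brain also lay higher in the class as a whole, while those for thalamus and spinal cord did not. Each of the 3 stood apart in its own region, where the median log2 difference from the other tissues was 3.86 against 0.01 to 1.505 in the other 7 for cerebellum, 2.72 against 0.14 to 1.09 for caudate nucleus and 3.58 against 0.27 to 0.98 for fetal brain. Of 9 cerebellum genes 6 were higher (median 1.10), with ZIC1 at 3.78, CALB1 at 2.79 and PVALB at 2.68, and GRM4 at 0.20 did not pass. The 14 genes of developing neurons held 9 higher genes (median 1.19), with CRMP1 at 2.62, NNAT at 2.47 and TUBB3 at 2.22, while DLX2 lay at −0.13. Of 9 striatal genes 3 were higher (median 0.87), the neuropeptide precursors TAC1 (2.24) and PENK (1.92) and the receptor GPR6 (1.42), while RARB lay at 0.05. Camera passed these 3 lists (adjusted p = 0.000489, 0.000369 and 0.00392), but not with an estimated correlation (adjusted p = 0.335, 0.335 and 0.472). Of 12 thalamus genes 4 were higher, among them LHX2 (2.12), CALB2 (2.03) and SLC17A6 (1.95), and LEF1 lay at 0.03. That list had a median of −0.002, a mean of 0.50 and a camera direction upward (adjusted p = 0.291). None of the 8 genes of the HOX patterning list of spinal cord passed (median −0.428, camera adjusted p = 0.284).

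Lists of epithelium, connective tissue and smooth muscle lay lower in the central nervous system. Of 14 epithelial keratins and junction genes 12 were lower (median −1.98), including KRT18 (−2.99) and KRT19 (−2.81), and OCLN (−0.54) stayed under a 2-fold difference. Of 13 smooth muscle genes 10 were lower (median −2.22), including MYL9 (−2.83), TAGLN (−2.78) and CNN1 (−2.64), while SYNM lay at 0.12. Of 17 extracellular matrix genes 9 were lower (11 adjusted over the list alone, median −1.25), including COL3A1 (−3.80) and COL1A1 (−3.18), while SPARC lay at 0.10. Of 14 immediate early and stress genes 6 were lower (median −0.999), including MYC (−2.56), ZFP36 (−2.38) and KLF6 (−1.73), while EGR1 lay at −0.37. Spinal cord stood apart from this, with a list median of 0.58 against −1.12 to −0.73 in the other 7 regions and ZFP36 at 709.7. Of 16 ribosomal proteins 5 were lower (median −0.84), including RPL8 (−1.42), RPS3 (−1.36) and RPL10A (−1.25), while RPL37A lay at −0.27. Camera passed these 5 lists (adjusted p = 5.45e-05, 0.00103, 0.000443, 0.00181 and 8.92e-08, in this order), but not with an estimated correlation (adjusted p = 0.541, 0.764, 0.7, 0.715 and 0.437). Of 27 cell cycle genes 3 were lower (4 adjusted over the list alone, median −0.64), with TOP2A at −1.47 and MCM5 at −1.08, and camera passed them (adjusted p = 0.00577) but not with an estimated correlation (adjusted p = 0.922). Of 16 T cell genes 2 were lower (3 adjusted over the list alone), CD3D (−1.18) and CD6 (−1.16), and camera passed that list (adjusted p = 0.0321) but not with an estimated correlation (adjusted p = 0.922). The remaining largest downward differences were IGLC1 (−4.08), IGLV1-44 (−3.94), IGKC (−3.70), VAMP8 (−3.59), LYZ (−3.57), S100A11 (−3.52), CFD (−3.39) and S100A4 (−3.23).

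Some lists held members that moved both ways in the central nervous system. Of 11 microglia and macrophage genes, the microglial chemokine receptor CX3CR1 was higher (2.70, adjusted p = 3.35e-08), while the scavenger receptor CD163 (−1.93) and the lipopolysaccharide co-receptor CD14 (−1.23) were lower and ITGAM lay at −0.10. Of 23 plasma protein genes, TF (4.37) and TTR (3.50), carriers of iron and of thyroid hormone, were higher and SERPINA1 (−2.28) was lower. Of 12 muscle calcium handling genes, ATP2A2 (1.66) and RYR2 (1.18), a calcium pump and a calcium release channel, were higher and PLN (−1.62) was lower. Camera passed none of these 3 lists (adjusted p = 0.612, 0.411 and 0.968). The imprinted genes PEG3 (2.40) and PEG10 (1.79) were higher, while DLK1 lay at −2.04 (adjusted p = 0.0548).

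RNA quality and scan day moved with this comparison. The GAPDH 3′ to 5′ ratio was 1.64 ± 0.472 (SD, n = 8) in the central nervous system and 1.20 ± 0.372 (SD, n = 27) in the other tissues. The actin ratio had a median of 1.965 (1.047 to 4.588) in the class against 1.193 (0.548 to 7.521). With the GAPDH ratio as a covariate 949 of the 1061 higher and 499 of the 685 lower genes still passed by limma. With the actin ratio 930 and 510 did, and without the arrays with a GAPDH ratio above 2 it was 960 and 479. The median log2 difference over all tested genes was −0.12. Camera compares each list with the other genes, so its tests are relative to that shift. With scan day as a block 771 of the 1061 higher and 278 of the 685 lower genes still passed, 411 genes passed as lower in all, and 1 lower gene turned direction. Over the higher genes the median log2 difference was 1.75, 0.93, 2.02 and 1.73 within scan days 3, 5, 6 and 8, and over the lower genes it was −1.81, −0.56, −1.15 and −1.45. On day 5 the class stood against a single other tissue, pituitary gland. With the block the list medians were 2.96 for the synaptic list (0.87 on day 5 to 3.77 on day 6), 2.46 for oligodendrocyte genes, 1.75 for astrocyte genes, 0.514 for striatal genes and −1.24 for epithelial keratins and junctions. The ribosomal list median was −0.529 with quantile normalization and −0.47 with the block, and ran from −0.77 within day 5 to 0.02 within day 8. Smooth muscle genes lay at −1.28 with the block and at 0.32 within day 5.

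**Figure D1:**
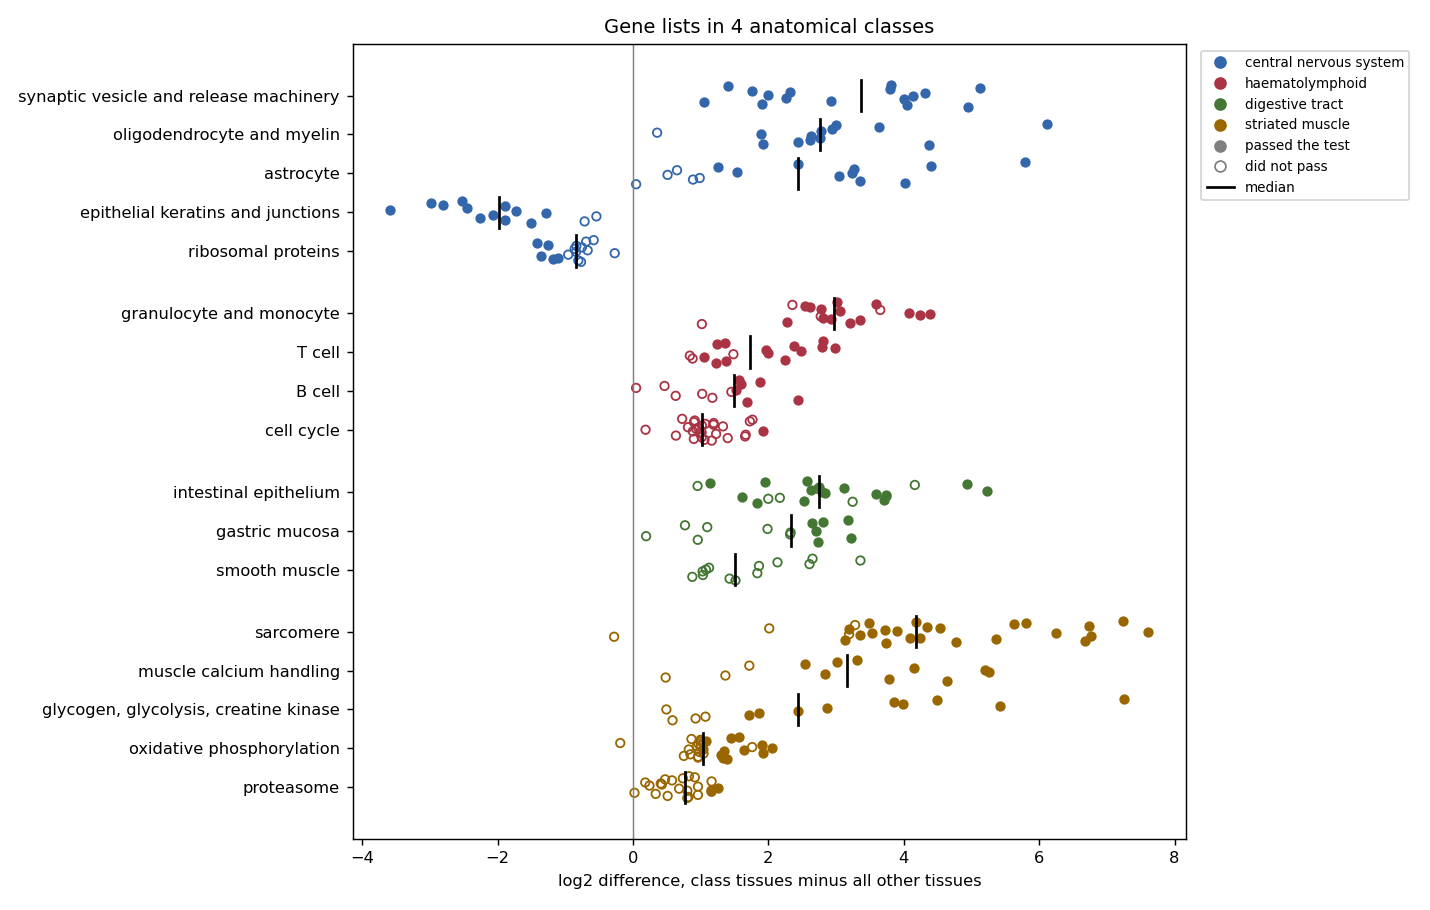
Log2 difference (horizontal axis) of each tested gene of 17 lists between the tissues of an anatomical class and all other tissues, with the lists on the vertical axis and 1 colour per class. Filled points passed the test, open points did not, and black bars mark list medians, such as 3.36 for synaptic genes in the central nervous system and 4.17 for sarcomere genes in striated muscle.

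Haematolymphoid tissues were set apart by granulocyte and T cell transcripts. S100A9 (a calcium-binding protein abundant in neutrophils) was 21.0-fold higher than in the other tissues (mean log2 intensity 11.07 ± 2.27, SD, n = 3, against 6.68 ± 1.22, SD, n = 32, adjusted p = 0.000214), from 351.9 in thymus to 7339 in bone marrow. RAC2, a GTPase of blood cells, was 13.2-fold higher (11.10 ± 0.55 against 7.38 ± 0.84, SD, n = 3 and 32, adjusted p = 5.02e-06), and all 3 tissues lay above the highest other value, 731.9 in thyroid. SOX9, a transcription factor of many epithelia and of glia, was 7.11-fold lower (adjusted p = 0.00517), and DDAH1 5.81-fold lower (adjusted p = 0.000212). In all, 300 genes were higher and 44 lower. The other largest differences upward were S100A12 (4.24), S100A8 (4.07), CD52 (3.84), NKG7 (3.79), SRGN (3.71), MMP9 (3.66), CST7 (3.64), IL1R2 (3.63), ELANE (3.59) and CORO1A (3.54). ELANE, neutrophil elastase, lay at 6800 in bone marrow and 19.2 in spleen. The other largest differences downward were CAMK2N1 (−2.96), GPRC5B (−2.89), PLAAT3 (−2.64), ATP1B1 (−2.42), MAOB (−2.36), TMEM47 (−2.24), PFN2 (−2.05), FERMT2 (−2.01), DSTN (−1.997) and SDC2 (−1.99).

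Of 18 granulocyte and monocyte genes 14 were higher in the haematolymphoid tissues (18 adjusted over the list alone, median 2.97), and CEBPE at 1.02 was among those that did not pass over all genes. Of 16 T cell genes 13 were higher (14 adjusted over the list alone, median 1.72). They included LCK (2.98) and CD3D (2.81), which reached 1487 and 2214 in thymus, and CD247 (2.80), while TRAT1 lay at 0.84 (adjusted p = 0.334). Both lists passed camera (adjusted p = 2.45e-29 and 1.96e-24) and also with an estimated correlation (adjusted p = 0.00552 and 0.00606). Of 12 B cell genes 6 were higher (8 adjusted over the list alone, median 1.49), including POU2AF1 (2.44), CD79A (1.88) and TCL1A (1.69), while BLK lay at 0.05. Of 11 microglia and macrophage genes 3 were higher (7 adjusted over the list alone, median 1.52), including AIF1 (2.87) and TYROBP (2.62), while CX3CR1 lay at −0.10. Camera passed both lists (adjusted p = 1.24e-08 and 1.35e-05), but not with an estimated correlation (adjusted p = 0.111 and 0.536).

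Single genes passed in 3 further lists of the haematolymphoid tissues. The replication helicase subunit MCM5 was higher (1.92, adjusted p = 0.043) among 27 cell cycle genes with a median of 1.02, and TOP2A lay at 1.76 (adjusted p = 0.308). The haemoglobin gene HBD was higher (2.86, adjusted p = 0.0461) among 9 erythroid genes with a median of 1.68, at 8408 in bone marrow and 12.2 in thymus. Against the median of the other tissues the erythroid list lay at 5.12 in bone marrow, while thymus and spleen ranked below placenta at 0.58. HLA-DOB was higher (1.93, adjusted p = 4.35e-05) among 8 MHC class II genes with a median of 1.81, and HLA-DRA lay at 2.05 (adjusted p = 0.294). Camera passed these 3 lists (adjusted p = 1.32e-10, 0.000288 and 0.00145), but not with an estimated correlation (adjusted p = 0.77 for each). No gene passed among 28 oxidative phosphorylation genes (median −0.48, camera adjusted p = 2.61e-06, and adjusted p = 0.946 with an estimated correlation), where NDUFA5 lay at −1.23. Ribosomal proteins (median 0.45, camera adjusted p = 0.0112) held no passing gene either, and their median fell to 0.142 with quantile normalization and 0.182 with scan day as a block. Smooth muscle (median −1.21), synaptic (−0.94), astrocyte (−0.98), keratin and junction (−0.74) and extracellular matrix genes (−0.69) lay lower by camera (adjusted p from 0.00486 to 0.0471), with SOX9 their only passing member. With an estimated correlation these 6 lists had an adjusted p = 0.956. The other tissues included those of the central nervous system, where synaptic and astrocyte genes lay high, so lower values of those lists may reflect only that.

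Fewer genes passed when 1 of the 3 haematolymphoid tissues was left out, while most kept a 2-fold difference. Without bone marrow 167 genes were higher and 4 lower, and 253 of the 300 and 34 of the 44 still differed at least 2-fold. Without spleen 199 were higher and 27 lower, and 281 and 44 still differed so. Without the central nervous system among the other tissues 216 of the 300 higher and 25 of the 44 lower genes still passed. In that setting 289 and 42 still differed at least 2-fold. With scan day as a block 217 of the 300 higher and 17 of the 44 lower genes still passed. The median log2 difference of the higher genes was 1.33, 1.79 and 1.96 within scan days 2, 3 and 8, and that of the lower genes −1.22, −1.29 and −2.18. The granulocyte list median was 2.91 with the block and ran from 0.65 on day 2 (thymus) to 6.30 on day 8 (bone marrow). The T cell list median was 1.62 with the block, from 1.09 on day 8 to 3.12 on day 2, and the B cell median 1.41, from 0.57 to 2.21. With the block the synaptic list lay at −0.554, astrocyte genes at −0.64, and keratins and junctions at −1.163.

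Intestinal epithelial transcripts set the digestive tract apart, most of all small intestine and colon. KRT20, a keratin of intestinal epithelium, was higher than in the other tissues (adjusted p = 1.11e-15), at 378.5 in stomach to 1533 in small intestine, with 25.2 in fetal lung as the next value. LGALS4, a galectin of the gut epithelium, was 30.4-fold higher (mean log2 intensity 11.19 ± 1.25, SD, n = 3, against 6.26 ± 0.70, SD, n = 32, adjusted p = 1.29e-09). TSPAN8, a tetraspanin, lay within 2361 and 2639 in the 3 tissues and was 27.4-fold higher (adjusted p = 9.23e-06). In all, 123 genes were higher and 2 lower, the kinase CDKL3 (−1.41, adjusted p = 0.0242) and the DNA repair nuclease ERCC4 (−1.14, adjusted p = 0.0133). Further large differences upward were AKR1B10 (4.63), SPINK1 (4.53), AGR2 (4.41), JCHAIN (4.37), REG1A (4.17), FCGBP (3.82), ZG16 (3.81), SI (3.74) and CLCA1 (3.73). SPINK1 and REG1A were higher still in pancreas, at 8629 and 9278. The brush border enzyme sucrase-isomaltase, SI, lay at 2033 in small intestine and 7.1 in stomach. CHN1 (−2.29), TTR (−2.28), SLC1A3 (−2.07) and RRAGD (−2.07) had larger negative differences than the 2 lower genes but did not pass (adjusted p from 0.17 to 0.784).

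Of 23 intestinal epithelium genes 17 were higher in the digestive tract (22 adjusted over the list alone, median 2.75). The list passed camera (adjusted p = 9.58e-63) and also with an estimated correlation (adjusted p = 5.15e-05). As a median log2 difference from the median of the other tissues it lay at 4.88 in small intestine and 4.46 in colon. Salivary gland (0.37) and liver (0.29) came next, so stomach lay no higher than liver. FABP1 lay at 4.16 (adjusted p = 0.124), with 6082 in fetal liver, and FABP2 (0.95) stayed under a 2-fold difference. Of 13 gastric mucosa genes 6 were higher (10 adjusted over the list alone, median 2.33). The gastric lipase LIPF (3.22) lay at 8467 in stomach and 12.2 in colon, GKN1 (3.18) at 9220 and 0.7, TFF1 (2.81) at 6712 in stomach, and GAST at a log2 difference of 0.19 did not pass. Camera passed the gastric list (adjusted p = 2.02e-16), but not with an estimated correlation (adjusted p = 0.064). None of 14 keratin and junction genes passed over all genes (7 adjusted over the list alone, median 2.14), with KRT19 at 3.69 and EPCAM at 3.24, nor did any of 13 smooth muscle genes (median 1.51), with MYH11 at 3.36 and ACTG2 at 2.65. Camera passed both (adjusted p = 1.36e-08 and 8.83e-05), but not with an estimated correlation (adjusted p = 0.653 and 0.875). Oxidative phosphorylation (median 0.39, COX7B at 0.83) lay higher by camera, and glutamate and GABA (−0.55, GAD1 at −1.51), astrocyte (−0.82, GFAP at −1.72), proteasome (−0.16) and synaptic genes (−0.69, SNAP25 at −1.31) lower (adjusted p from 0.00158 to 0.0288). No member of these 5 lists passed, and their adjusted p = 0.875 with an estimated correlation. The other tissues included those of the central nervous system, where glutamate and GABA, astrocyte and synaptic genes lay high. Lower values of those lists here may reflect only that.

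Fewer genes passed in the digestive tract without small intestine, with 46 higher and 0 lower by limma, and without colon, with 64 and 1. Of the 123 higher genes 103 and 117 still differed at least 2-fold in these settings. Without the central nervous system among the other tissues 79 were higher, while 122 of the 123 still differed at least 2-fold. Without stomach 4 were lower. With scan day as a block 72 of the 123 higher and neither of the lower genes still passed. Day 3 held small intestine and colon beside other tissues and gave medians of 2.54 and −1.28 over the higher and lower genes, while stomach was alone on day 7. Within day 3 the list median was 4.24 for intestinal epithelium, 3.13 for keratins and junctions, 2.07 for smooth muscle and 0.06 for gastric mucosa.

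Contractile proteins set heart and skeletal muscle apart. TNNC1, the slow and cardiac form of the calcium sensor troponin C, was higher than in the other tissues (mean log2 intensity 12.20 ± 0.30, SD, n = 2, against 4.59 ± 1.36, SD, n = 33, adjusted p = 4.84e-07), at 4033 in skeletal muscle and 5427 in heart against a median of 2.6. The creatine kinase CKM and the actin ACTA1 were each 152-fold higher. CSRP3 lay at 2532 and 3887 against a median of 1.8, and ACTN2, which crosslinks actin at the Z-disc, at 3122 and 2573 against 5.2 (adjusted p = 1.33e-07). ITM2C was 12.8-fold lower (adjusted p = 0.0275), and PTPRF, a receptor phosphatase, 6.59-fold lower (adjusted p = 0.00781). In all, 254 genes were higher and 109 lower. Upward, MYL2 (6.73), MYOZ2 (6.68), TTN (6.25), SMPX (5.90), MYH6 (5.81), DES (5.77) and ANKRD2 (5.70) followed. For TNNC1, CSRP3, ACTN2, MYOZ2, MYH6 and ANKRD2 the mean of the other tissues lay below the pseudocount, so size and order depend on it. For all 12 of these largest genes the highest value outside the class was that of prostate, such as 2137 for TNNC1, 3960 for ACTA1 and 2600 for CKM. Downward, SPINT2 (−2.97), FGFR2 (−2.92), FKBP11 (−2.75), PLXNB2 (−2.51), PIEZO1 (−2.29), RNASET2 (−2.26), CHD3 (−2.11), ITPA (−2.10), DYNLL1 (−2.08) and TKT (−2.04) were the other largest.

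Of 27 sarcomere genes 23 were higher in striated muscle (26 adjusted over the list alone, median 4.17). TPM1 lay at −0.28 and did not pass with its brightest probe set, but at 6.36 with the probe set of largest variance. Of 12 muscle calcium handling genes 9 were higher (11 adjusted over the list alone, median 3.16), including PLN (5.26), CASQ2 (5.20) and HRC (4.64), while CACNA1C lay at 0.48. Of 13 glycogen, glycolysis and creatine kinase genes 9 were higher (9 adjusted over the list alone, median 2.43), including ENO3 (5.42) and the mitochondrial creatine kinase CKMT2 (4.49), while LDHA lay at 0.49. Of 28 oxidative phosphorylation genes 12 were higher (16 adjusted over the list alone, median 1.04), including UQCRC1 (2.06), COX7B (1.92) and NDUFS1 (1.90), while NDUFB8 lay at −0.19. These 4 lists passed camera (adjusted p from 2.59e-59 to 2.13e-23) and also with an estimated correlation (adjusted p from 1.13e-05 to 0.0264). Of 22 proteasome genes 2 were higher (4 adjusted over the list alone, median 0.77), with PSMB6 at 1.26 (adjusted p = 0.0119) and PSMC4 at 0.02, and camera passed the list (adjusted p = 1.76e-09) but not with an estimated correlation (adjusted p = 0.0794). Keratins and junctions lay lower (median −1.41, camera adjusted p = 0.0172, and adjusted p = 0.997 with an estimated correlation), with SPINT2 as the passing gene and CDH1 at −3.41 (adjusted p = 0.318). Adipocyte genes lay higher by camera (median 0.73, adjusted p = 0.0374, and adjusted p = 0.653 with an estimated correlation) with no passing gene, and FABP4 lay at 2.76 (adjusted p = 0.301).

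Without skeletal muscle, which leaves 1 striated muscle array, 90 genes were higher and 17 lower, and 189 of the 254 and 74 of the 109 still differed at least 2-fold. Without heart 68 genes were lower, and 227 and 96 still differed so. The median log2 difference over all genes was −0.11 in this comparison. With scan day as a block 224 of the 254 higher and 86 of the 109 lower genes still passed. The higher genes had a median of 2.33 within day 1 (skeletal muscle) and 1.57 within day 4 (heart), and the lower genes −1.75 and −1.15. With the block the sarcomere list had a median of 4.25 (4.28 on day 4, 6.46 on day 1), calcium handling 3.36, the glycogen list 2.67, oxidative phosphorylation 1.16 and proteasome 0.74. The adipocyte list fell to 0.293, and keratins and junctions lay at −2.667.

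Heart and skeletal muscle held different isoforms of the same contractile proteins. Heart held 48 genes at least 8-fold above skeletal muscle and skeletal muscle 60 above heart, on 1 array each and without a test. These 108 genes became 178 with a pseudocount of 3.775 and 56 with one of 60.4. The atrial light chain MYL7 lay at 3033 in heart and 7.9 in skeletal muscle, NDRG4 at 1299 and 6.3, and CDH2 at 783.1 and 5.0. The cardiac troponin I gene TNNI3 was 68.4-fold, the natriuretic peptide gene NPPB 46.4-fold and CNN1 33.9-fold higher in heart. In skeletal muscle the fast light chains MYL1 (6708 against 16.6) and MYL11 were 212-fold and 174-fold higher and fast troponin C, TNNC2, 119-fold. Fast troponin I, TNNI2, lay at 3615 against 7.1, MYBPC2 at 2304 against 2.7 and the fast myosin heavy chain MYH1 at 3279 against 12.9. Values below the pseudocount of 15.1 lie near background, so no fold is given for these genes. For MYL1, MYL11 and NPPB the lower value (16.6, 16.5 and 16.4) lay just above the pseudocount, so the size of their folds depends on it too. ACTA1 lay within 1.06-fold in the pair and TNNC1 within 1.34-fold.

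**Figure D2:**
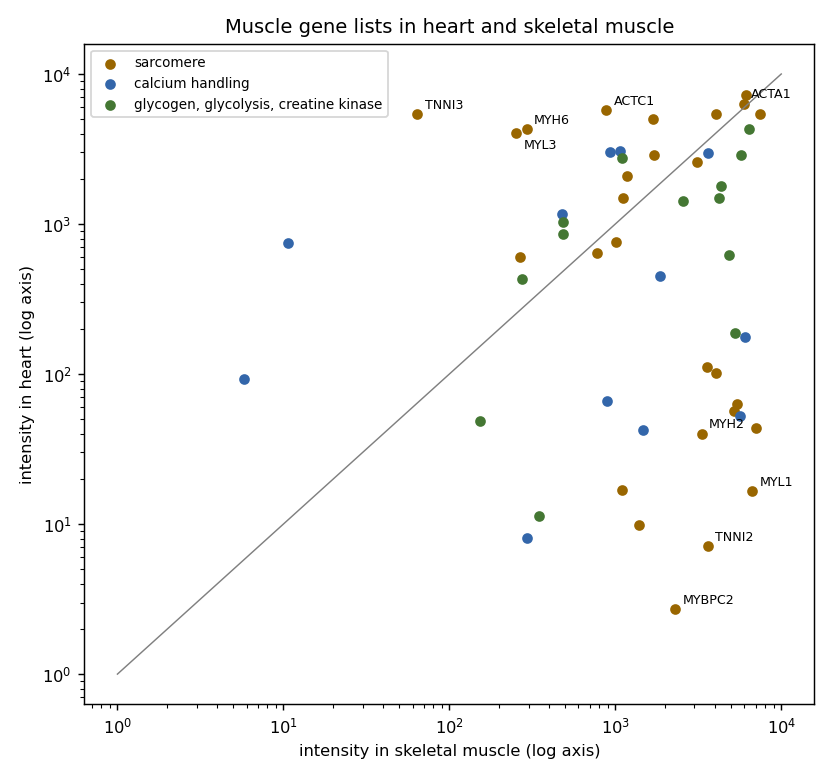
Intensity in heart (vertical log axis) against intensity in skeletal muscle (horizontal log axis) for the genes of the sarcomere, calcium handling and glycogen lists. There is 1 point per gene and 1 array per tissue, with a line of equality. MYL1 lies at 6708 in skeletal muscle and 16.6 in heart, and TNNI3 at 64.1 and 5404.

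In brain, lung and liver, 57 genes were at least doubled in the fetal array of all 3 organs and 55 were at least halved. When the direction of a single organ was turned around, 7 to 16 genes were found in place of the 57 and 7 to 19 in place of the 55. Upward, SLC4A1, an anion exchanger of red cells, lay at 38.4, 167.6 and 3005 in fetal brain, lung and liver against 10.8, 8.1 and 9.8, and PAFAH1B3 at 547.4, 388.9 and 50.5 against 13.6, 3.1 and 6.1. NT5DC2, HIC2, NREP, MYCN, PEG10, NNAT, IGF2BP3, COL1A1, PCLAF and TPX2 followed. IGF2BP3 (28.9, 100.5 and 222.0 against 2.9, 10.1 and 1.5) binds the messenger of a fetal growth factor, MYCN (320.9, 132.6 and 29.5 against 19.5, 1.4 and 5.8) is a transcription factor of dividing progenitors, and TPX2 (log2 differences of 1.34, 2.27 and 3.06) is a spindle protein. Downward, NNMT lay at 3.0, 3.5 and 4.0 in the fetal arrays against 23.4, 917.2 and 4870, HSD17B6 at 2.5, 2.6 and 5.4 against 92.2, 379.0 and 2395, and PLAAT3 at 11.2, 7.8 and 13.9 against 328.1, 201.5 and 486.1. BHLHE40 lay at 107.7, 8.5 and 9.9 against 357.4, 875.3 and 849.0. GADD45B, HLA-DRA (−1.02, −4.73 and −4.03), HLA-DPB1, MBNL2, IGHD, C3 (−1.01, −3.39 and −2.92), HLA-DPA1 and the class II invariant chain CD74 (−1.44, −3.16 and −2.59) followed. Values below the pseudocount lie near background, so the order of these genes depends on it. No gene passed the test over the 3 organs: by limma with organ as a block 0 genes were higher and 0 lower, and 1027 genes had an unadjusted p under 0.05. PLAAT3 had a mean of −3.69 ± 0.435 (SD, n = 3, adjusted p = 0.25), and every one of the 13 alternatives per direction also gave 0 genes. In total 3510 genes (32.2%) moved the same way in all 3 organs, where chance gives 25% for independent organs. The organs shared batches, though. Fetal brain and fetal liver were both on scan day 8 and chip lot B, brain and liver on day 6 and lot A. A batch difference could thus raise this share and the counts of 57 and 55. The Pearson correlation of the differences across genes was 0.095 between brain and liver, 0.232 between brain and lung and 0.249 between lung and liver.

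Cell cycle and fetal growth lists lay higher in the fetal arrays, and MHC class II genes lower. Of 27 cell cycle genes 7, 21 and 24 were doubled in brain, lung and liver, with list medians of 0.51, 1.37 and 2.76. CDC20, an activator of mitotic exit, lay at 17.6, 131.5 and 340.9 in the fetal arrays against 6.4, 3.7 and 11.7, and MKI67 at log2 differences of 0.26, 0.92 and 0.64. The fetal and imprinted growth list (11 genes) had medians of 0.79, 1.40 and 3.84, and the fetal plasma protein gene AFP lay at 8245 in fetal liver and 30.8 in liver. Erythroid genes had medians of 0.24, 0.998 and 4.67, extracellular matrix genes 0.18, 0.94 and 0.13, and ribosomal proteins 0.98, 0.22 and 0.84. All 14 genes of developing neurons were doubled in fetal brain (median 2.05, against 0.84 in lung and 0.75 in liver), with the transcription factor gene SOX11 at 1416 in fetal brain and 5.8 in brain. MHC class II genes had medians of −0.75, −3.05 and −1.71, with 4 of 8 halved in all 3 organs. Microglia and macrophage genes had medians of −0.62, −2.75 and −0.55, immediate early genes 0.15, −1.60 and −2.67, and oxidative phosphorylation genes −0.68, −0.54 and −0.03. P450 and conjugation genes had medians of 0.09, 0.15 and −3.41, with CYP2E1 at 11.4 in fetal liver and 5914 in liver. Surfactant and airway genes had medians of 0.04, −2.12 and 0.06, with SFTPD at 39.2 in fetal lung and 1072 in lung. Camera passed these 12 lists (adjusted p from 1.12e-16 to 0.0119), but none with an estimated correlation (adjusted p = 0.992 for each). No member passed over all genes, while adjusted over the list alone 23 cell cycle, 8 fetal growth, 6 developing neuron, 4 extracellular matrix and 1 ribosomal gene were higher and 6 MHC class II genes lower. The fetal and non-fetal arrays of each organ differed in both scan day and chip lot, so no batch gave a value within it and batch and stage cannot be told apart.

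**Figure D3:**
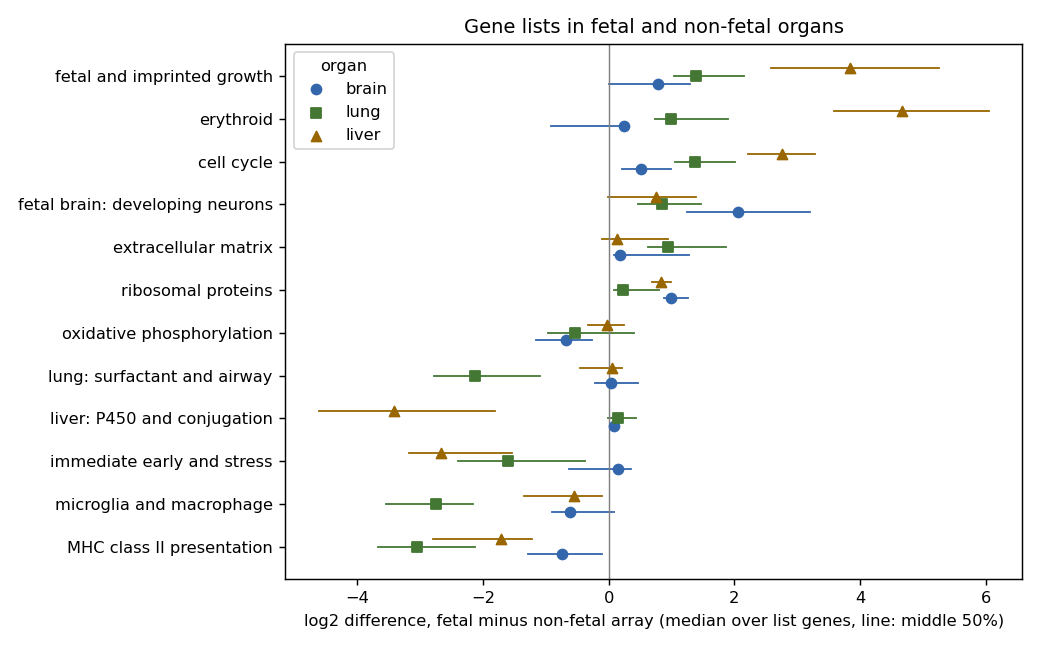
Median log2 difference between the fetal and the non-fetal array (horizontal axis) of the genes of 12 lists (vertical axis) in brain, lung and liver, with lines for the middle 50% of the genes. The cell cycle medians are 0.51, 1.37 and 2.76 and the MHC class II medians −0.75, −3.05 and −1.71.

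Across the 36 tissues, 454 gene and tissue pairs had a value at least 5 times that of the next tissue, each from a single array. Liver held 88 and testis 87, followed by fetal liver (29), pancreas (28), skin (28), skeletal muscle (23), bone marrow (21), placenta (19), small intestine (15) and stomach (13). Fetal and non-fetal arrays of an organ were not set against each other here. Large ratios were those of TFF2 in stomach (204-fold) and the cystatin CST1 in salivary gland (202-fold). The hormone genes POMC (6786 in pituitary gland) and INS (4239 in pancreas) and the protamine gene PRM2 (3636 in testis) lay at 13.9, 7.1 and 5.4 in the next tissue. Ratios were taken after adding the pseudocount of 15.1 to both values, so their size and order depend on it, most where the next value lay below it. This held for those 3 genes and for KRT33A, ODF2, DNTT, MUC16, ZP2 and TBX4. In pancreas the digestive enzymes CPA1 (109-fold) and PNLIPRP1 (108-fold) followed INS, and in small intestine the Paneth cell defensin DEFA6 stood 152-fold, DEFA5 40.7-fold and the hormone GIP 31.8-fold above the next tissue. In liver AGXT (73.2-fold), HPX and the prothrombin gene F2 led, in fetal liver AFP (43.6-fold), APOA2 and AHSG, and in bone marrow the granule proteins ELANE (70.6-fold), AZU1 and MPO. Adrenal gland was marked by the steroid enzymes HSD3B2 (54.2-fold), CYP11B1 and CYP17A1. Thymus was marked by CD1E (21.4-fold), DNTT and the recombinase RAG1, and kidney by KCNJ1 (12.9-fold) and the transporters SLC12A1 and SLC22A8. The surfactant genes SFTPD, SFTPB and SFTPC led in lung, from 33.6-fold to 34.9-fold. SFTPC also led in fetal lung (34.1-fold, at 6375), with SFTPB and TBX4. The hair keratin KRT33A (2182 in skin against 7.2), KRTAP1-3 and KRTAP9-9 led in skin, PAGE4 (30.8-fold), PSG2 and HSD3B1 in placenta, and CEACAM7 (16.9-fold), MS4A12 and CLCA4 in colon. CYTL1 (21.6-fold), BPIFA1 and MUC16 led in trachea and ZP2 (184.1 against 6.1), CRTAM and EN2 in cerebellum. Heart was led by MYL7 (90.4-fold), TNNI3 and NPPB, and skeletal muscle by MYH1 (66.1-fold), ATP2A1 and AMPD1. In pituitary gland TSHB (20.1-fold) and TBX19 followed POMC, in testis PRM1 (71.1-fold) and ODF2, in stomach GKN1 (151-fold) and LIPF, and in salivary gland CST2 and CST5. A ratio of 3 in place of 5 gave 823 pairs and a ratio of 10 gave 225.

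Marker lists fixed for single tissues ranked first in their own tissue in 24 of 25 cases, each above the 99th percentile of 10000 random lists matched on size and mean expression. The largest medians of log2 difference from the other tissues were 7.99 for salivary gland, 7.84 for pancreatic acinar enzymes, 7.07 for liver plasma proteins, 5.40 for skin and 5.28 for breast. Smaller medians were 2.25 for bladder urothelium, 1.69 for trachea and 0.66 for thalamus. The HOX patterning list of spinal cord had a median of 0.13 there, at the 80.6th percentile, and ranked 14th of the tissues.

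**Figure D4:**
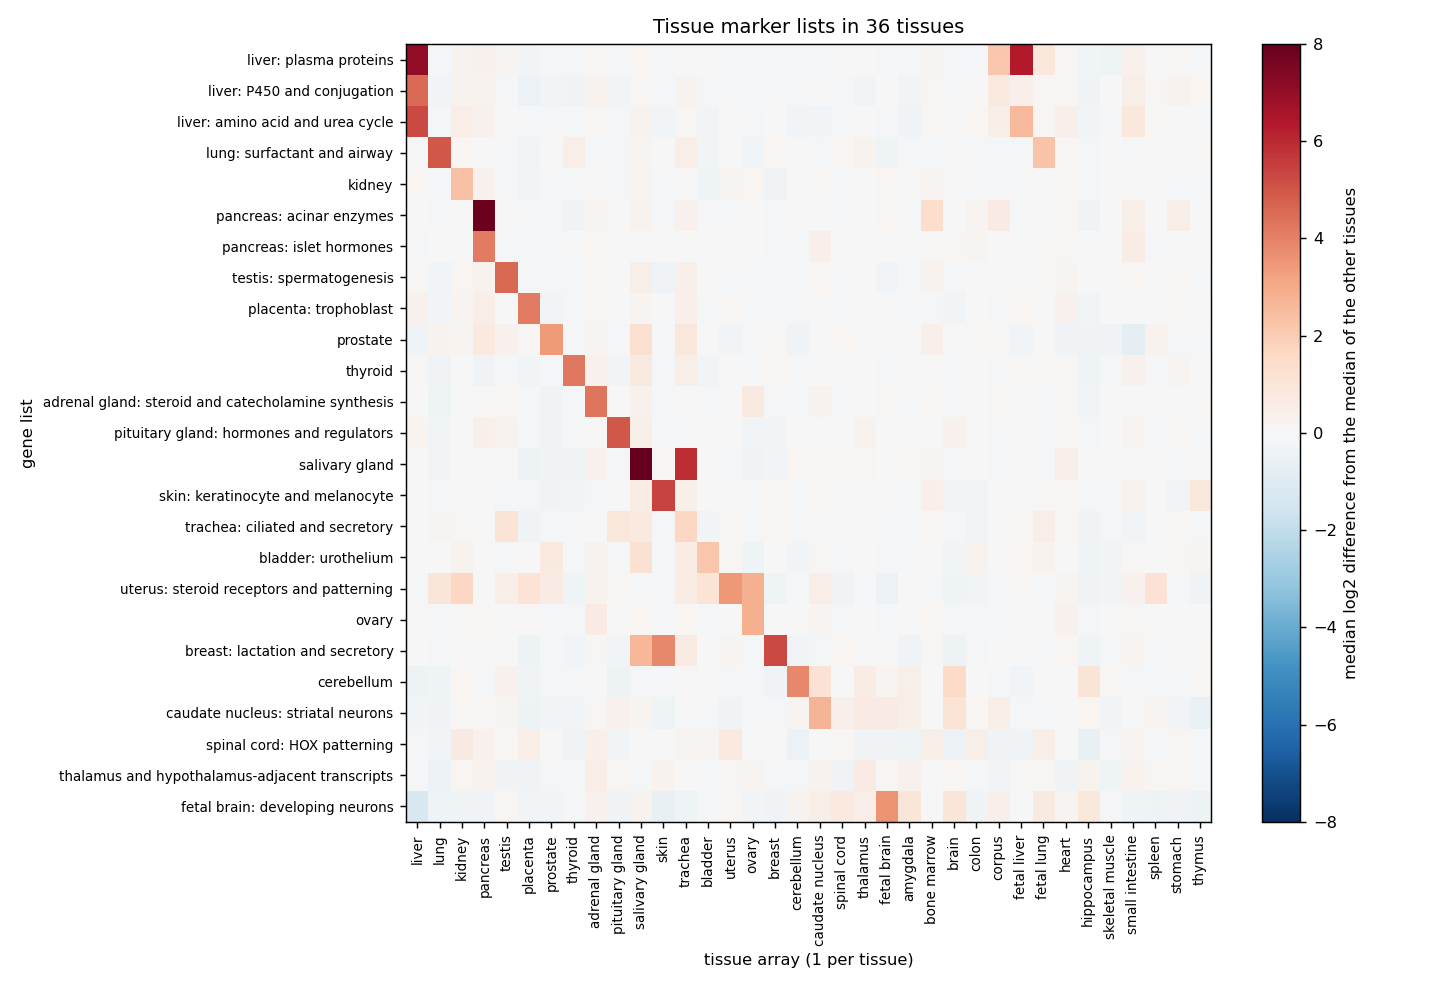
Median log2 difference of each of 25 tissue marker lists (vertical axis) from the median of the other tissues, in each of 36 tissue arrays (horizontal axis), as a colour scale. Each list is darkest in its own tissue, such as 7.99 in salivary gland, except the spinal cord list, whose median there is 0.13.

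Within the central nervous system, 164 genes had a value in 1 region at least 3 times that of the next of the 8 regions. Cerebellum held 50, spinal cord 43, fetal brain 42, caudate nucleus 20 and thalamus 9, while brain, amygdala and hippocampus held 0. A gene shared by close regions cannot reach this ratio. Amygdala had a Spearman correlation of 0.966 with hippocampus, and brain of 0.931 with amygdala. A count of 0 therefore does not mean that a region lacked distinctive genes. In cerebellum the protocadherin-like FAT2 was 19.4-fold above the next region, while CRTAM lay at 353.5 against 13.4 and ZP2 at 184.1 against 2.8. In fetal brain SOX11 was 24.9-fold, SOX4 14.7-fold and DCX, a microtubule protein of migrating neurons, 12.8-fold above. In caudate nucleus ANO3 was 11.1-fold, the striatal phosphodiesterase PDE10A 7.99-fold and COCH 7.47-fold above, and in thalamus RGS16 10.5-fold and the transcription factor gene TCF7L2 5.71-fold above, with EPN3 at 215.9 against 7.5. Spinal cord was marked by HOXB6 (156.0 against 4.7), HOXB2 (8.43-fold) and RGS1 (7.22-fold). HOXB6 and HOXB2 were higher outside the central nervous system, at 217.3 in uterus and 555.1 in fetal lung. For CRTAM, ZP2, EPN3 and HOXB6 the next region lay below the pseudocount of 15.1, so no fold is given. With 4 times the pseudocount 79 genes lay above this ratio.

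Of 11929 genes, 3149 (26.4%) lay above the median of all values in all 36 tissues, 609 in exactly 1 tissue and 1013 in none. Of the genes above it in 1 tissue, testis held 128, salivary gland 45 and bone marrow 35. The number of genes above it ran from 6357 in skeletal muscle to 7424 in small intestine. All 16 ribosomal proteins, 25 of 28 oxidative phosphorylation genes and 19 of 22 proteasome genes lay above it in all 36 tissues. Their median tau, an index from 0 for even to 1 for single-tissue expression, was 0.123, 0.210 and 0.219, against 0.841 for acinar enzymes and 0.852 for salivary gland genes. Halving the level gave 5044 genes in all tissues and doubling it 1416.

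Central nervous system tissues resembled each other more than other tissues did. The Spearman correlation across genes, which are not independent replicates, had a median of 0.878 within the class (0.774 to 0.966), 0.654 between the class and other tissues and 0.751 among the others. Amygdala and hippocampus were closest, at 0.966, and prostate and bladder were the closest pair outside the class, at 0.907. Fetal brain lay at 0.871 from brain, fetal liver at 0.764 from liver, and fetal lung was nearest to uterus at 0.811. Pituitary gland was nearest to hippocampus at 0.831, and bone marrow and hippocampus were farthest apart at 0.517.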

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

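The tests on the prostate and corpus arrays were chosen after the results were seen, and the other tests of this part before. Outliers were sought among the 8 central nervous system tissues, where the gap of the highest or lowest tissue to its nearest neighbour was divided by the whole range and compared with the 95% critical value of Dixon. Of 142 genes, lists and 3′ to 5′ ratios 29 exceeded it. They were 14 in spinal cord, 9 in fetal brain, 3 in caudate nucleus, 2 in cerebellum and 1 in brain. About 1 in 20 would exceed it if all were independent draws from 1 normal distribution. Some items were fixed as markers of single regions, and lists share genes with single items, so that rate does not measure chance here.

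Fetal brain stood apart with lower MBP (gap over range 0.699, intensity 1540), TF (0.66), PEG3 (0.584), PLK1 (0.666, intensity 11.6) and KCNA1 (0.639, intensity 10.3) and with higher RPL10A (0.667, intensity 1567). Its lists of developing neurons (0.783, median 3.58 against 0.27 to 0.98), fetal and imprinted growth (0.72) and ribosomal proteins (0.552, median 0.24 against −1.23 to −0.57) lay above those of the other regions. Spinal cord stood apart with lower SYNGR3 (0.566), GAP43 (0.606), GAD1 (0.558) and ATP2A2 (0.627), and its synaptic list lay at a median of 1.38 against 2.71 to 3.85 (0.537). It was higher in LYZ (0.716), LTF (0.807), S100A11 (0.56), ENG (0.531), MYL9 (0.617), ZFP36 (0.59, intensity 709.7), HOXC6 (0.527) and HOXB7 (0.549). Its immediate early and stress list lay at 0.58 against −1.12 to −0.73 (0.77). Caudate nucleus stood apart with higher GPR6 (0.743) and striatal list (0.63), cerebellum with a higher cerebellum list (0.612) and lower FLT1 (0.594), and brain with lower CCNB2 (0.534, intensity 3.3). KRT7 in caudate nucleus (0.68, intensity 5.6) gives no evidence of a difference, since all 8 of its values lay below the pseudocount of 15.1. PLK1 and KCNA1 in fetal brain and CCNB2 in brain also lay below it, as did the other 7 regions for LYZ and LTF, so the size of these distances is uncertain.

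The 1061 genes higher in the central nervous system came from arrays with a higher GAPDH 3′ to 5′ ratio and from few scan days. A 3′ signal bias alone would leave fetal brain near the other tissues, since its ratio of 0.88 lies below their median of 1.13. The median log2 difference of fetal brain over the 1061 genes was 1.62. Fetal brain was itself among the tissues used to call these genes, so that value is partly set by the selection. When fetal brain was left out, 1012 of the 1061 genes still passed by limma, so most calls did not depend on it. With the GAPDH ratio as a covariate 949 still passed. Scan day alone would remove most of the differences, but 81.1% of the genes kept a log2 difference of at least 1 with scan day as a block. All of these values were taken on genes called from the same arrays. They argue against either as the whole cause of the 1061 calls, while a smaller part in the size of the differences was not excluded. The tissue class named by the labels stays the candidate explanation, as a hypothesis, since it was tested on the same data.

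Chance as a source of the class counts was tested with 100 splits of the tissues into groups of the same sizes, the real one included. For the central nervous system 1 split gave as many higher and 1 as many lower genes, the real one, with 96 and 75 as the highest other counts against 1061 and 685. The 96-gene split itself held 5 central nervous system tissues. For haematolymphoid tissues 1 split gave at least 300 higher genes (highest other 233) and 3 gave at least 44 lower genes (highest other 64). For the digestive tract 3 splits, the real one included, gave at least 123 higher genes (highest other 318). Few splits reached this count, but another grouping exceeded it, so the splits do not exclude chance for it. As 9 splits gave at least 2 lower genes (highest other 47), chance was not excluded there either. The larger digestive counts came from groups of central nervous system tissues, such as amygdala, caudate nucleus and fetal brain, a structure of the samples. For striated muscle 3 splits gave at least 254 higher genes (highest other 333, fetal liver with testis) and 2 gave at least 109 lower genes (highest other 195, bone marrow with salivary gland). The real fetal split and all 10 splits gave 0 genes in either direction, and 10 splits are too few for a share under 0.05.

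The prostate array held sarcomere transcripts, with a list median of 4.68 and 26 of 27 genes at least doubled. RNA of the skeletal muscle sample mixed into it would put nearly all abundant muscle transcripts at 1 share. Of 40 such genes 15.0% lay over 3-fold from their median share of 23.0%, within the 20% allowed. That bound was set after the results were seen, and it alone does not exclude mixing. Slow-fibre genes had a median share of 37.7% (19.3% to 63.6%) and fast-fibre genes of 11.3% (0.823% for MYH1 to 45.1%), a ratio of 3.32. Mixing at 1 share would give both the same median, so these values argue against it as the only source, although the ranges overlapped. Muscle of another fibre mix may account for the signal. A part from either source is not excluded, and whether muscle was part of the tissue taken was not tested.

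The corpus array, outside every comparison, had raised lists of oligodendrocyte (median log2 difference 4.169), plasma protein (2.136), astrocyte (2.041) and synaptic genes (1.489). A raised level of dim probe sets would raise the genes of other source tissues as well, but only 7.7% of 13 other sources reached at least 50% of the liver share, which argues against it for the plasma protein list. A small share of liver RNA could account for part of that list, since 93.1% of 58 liver genes lay above the median of the other tissues, at a median share of 1.12%. On pancreas, the next array, 47 of the 58 did, and the median of 33 arrays was 26. ALB at 1050, TTR at 5316 and TF at 4408 lay far above that share, so sources other than liver RNA stay open for them. TF and TTR were also higher in the central nervous system, and TF is in the oligodendrocyte list as well. The brain array held TF at 1718.5 and TTR at 1538.4, but ALB at only 16.0. No biological explanation was tested.

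Of the lists in the fetal comparison 2 had medians beyond 0.5 in opposite directions in different organs, others had smaller medians of opposite sign, and these differences were not tested. Oligodendrocyte and myelin genes lay at a median of 0.615 in lung and −1.557 in brain, and plasma protein genes at 0.819 in lung and −0.524 in liver.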

How the results depend on the processing

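The alternatives with a GAPDH or actin covariate, without the stopped fluidics arrays and without the arrays of GAPDH ratio above 2 were chosen after seeing the data. Of all alternative counts 173 stayed within 1.5 times the reported one and 41 did not, and unless stated the cause was not tested. With 4 times the pseudocount, which shrinks differences of dim genes, the counts were 703 higher and 315 lower for the central nervous system, 17 lower for haematolymphoid, 0 lower for digestive and 40 lower for striated muscle tissues, 79 region genes and 56 genes apart in heart and skeletal muscle (178 with a pseudocount of 3.775). Without a minimum fold, by construction, 1787 and 1697 genes passed in the central nervous system. Scan day as a block gave 411 lower genes there and 25 in haematolymphoid tissues.

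Leaving out 1 tissue at a time gave 1014 to 1084 higher and 646 to 756 lower genes for the central nervous system, 167 to 269 and 4 to 35 for haematolymphoid tissues, 46 to 137 and 0 to 4 for the digestive tract, and 90 to 225 and 17 to 68 for striated muscle. With 1 muscle tissue left, its spread is assumed to be that of the other tissues. Without the stopped fluidics arrays, which include bone marrow and skeletal muscle, the haematolymphoid counts were 177 and 7 and the striated muscle counts 83 and 13. Haematolymphoid lower genes numbered 29 with the GAPDH covariate and 27 without GAPDH ratios above 2. Digestive higher genes numbered 79 without the central nervous system, while 122 of the 123 kept at least a 2-fold difference. The 2 digestive lower genes became 0 with a stricter filter, 5 with all probe sets, 4 with the largest-variance probe set, with chip lot as a block or without stopped fluidics, and 1 without GAPDH ratios above 2.

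Tissue-enriched pairs numbered 823 at 3-fold and 225 at 10-fold, by construction, and genes above the level in all tissues 5044 at a level of 24.05 and 1416 at 96.2. TPM1 in striated muscle reversed from −0.28 to 6.36 with the largest-variance probe set. The marker lists ranked first in 24 of 25 cases under every alternative run, and the fetal counts stayed 0, which is no sign of stability, since 0% of genes with a simulated log2 difference of 2 were recovered there. Named genes kept direction and call in 2547 of 2746 gene and setting pairs for the central nervous system, 1260 of 1441 for haematolymphoid, 836 of 911 for digestive and 704 of 796 for striated muscle tissues. Leaving out GAPDH ratios above 3 was not run because no array exceeds 3, nor was a batch block for the fetal comparison, where the arrays of an organ lie in different batches. Ratios against values near or below the pseudocount depend on it.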

Other observations

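No test of this part was planned, and the values below carry no test unless one is named. Cell type lists were high in some tissues outside their class. Thyroid held B cell genes at a median log2 difference of 1.64 from the other tissues (10 of 12 at least doubled), MHC class II genes at 2.35 and T cell genes at 1.11, and pancreas held B cell genes at 1.26. Erythroid genes lay at 5.12 in bone marrow and 4.23 in fetal liver. Cell cycle genes lay highest in fetal liver (2.45, 26 of 27 at least doubled), followed by bone marrow (1.87), and at 1.48 in uterus. Extracellular matrix genes lay at 2.40 in fetal lung, and endothelial genes at 1.14 in placenta and 1.08 in lung.

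Some marker lists were also raised in other tissues. The salivary gland list lay at 5.92 in trachea, the lactation list at 3.85 in skin, the adipocyte list at 1.59 in skin and the keratinocyte list at 0.93 in thymus. Pancreatic acinar enzymes lay at 1.42 in bone marrow (10 of 13 at least doubled), and plasma protein genes at 0.84 in fetal lung. The corpus array, whose label names no organ, was nearest to spinal cord, with a Spearman correlation across genes of 0.933.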
